A study of Mus musculus with 6 samples.

How the data were processed

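PU.1 ChIP-seq peak lists of mouse iBN cells were analysed: 2 libraries from cells induced with 1000 ng per ml of doxycycline for 72 hours, 2 libraries from uninduced cells, and 1 merged list per condition. Per the labels' protocols, cells were cross-linked with formaldehyde, chromatin was sonicated, and 300 ug of chromatin per sample was precipitated with a polyclonal antibody against PU.1. Libraries were made from fragments of 100 to 300 bp. Input libraries of both conditions (2 in all) are labelled in the series and were not analysed here.

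The submitters' processing notes name Trim Galore, Bowtie and MACS 1.4.1 and the mouse build mm9. Each deposited list has 5 columns: chromosome, start, end, a MACS peak name and a score. The score is 1 value per peak as the authors deposited it, with a minimum of 50 in each list, and its scale is not given in the sources used here. MACS scores grow as the p-value of a peak falls. The score was used to rank, describe or filter peaks within a list, and in 1 rule across the 2 replicate lists of a condition, the choice of the regions named. Whether an input served as the control of peak calling, which reads were removed and how the replicates were merged are not given in the sources used here. Each merged list holds peaks found in neither replicate, so it is not a plain union of the replicate lists. Because a list shows only what passed the authors' threshold, an absent peak means that none was called, not that PU.1 was absent. No read totals were given, so depth is unknown and peak numbers were not corrected for it.

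All results below were computed from these lists with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Samples were grouped by their titles. Peaks were taken as overlapping when they had at least 1 bp in common. The peaks of the 4 libraries were merged into regions, and a region was called shared with a peak in all 4 libraries, gained with a peak in both induced and neither uninduced library, lost with a peak in both uninduced and neither induced library, and mixed otherwise. Peak number and covered length were compared with an exact two-sided permutation test over libraries. Scores of 2 sets of peaks within a library were compared by the area under the curve, where 0.5 is no difference, with a 95% interval from 500 resamples of the chromosomes. Distances to shared regions, edge to edge within 10 kb, were compared with 1000 circular rotations along each chromosome. Chromosomes were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 20 chromosomes; Y was left out. Intervals of shares are 95% Wilson intervals and cover counting error only.

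The regions named are the 10 gained and the 10 shared regions with the highest value of the lower induced score, and the 5 lost regions with the highest value of the lower uninduced score. This rule, the comparisons and the alternatives were set before the data were examined, except for 2 alternatives added later: leaving out regions with a peak in the other condition's merged list, and counting windows of 100 kb once per class. The distance test of lost regions, their chromosome test with its alternatives, and the widths of peaks by class were added later too. The rank of shared regions by segment was also chosen after the chromosome shares were seen. The alternatives tried were an overlap of at least 50% of both intervals, a score of at least 100, lists of equal length (31960 peaks), other distance windows (2 and 50 kb), the merged lists, leaving out each library and a block by replicate number.

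Tests of promoter share, of 16 fixed gene lists and of the PU.1 motif, also set before, were not run, because they need a gene annotation or a sequence of mm9 and the gene table at hand belongs to another build. No gene is therefore named.

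The functions were tested on simulated lists with 3000 gained, 500 lost and 4000 shared regions drawn with the widths of the real peaks. With both overlap rules 100% of each class was recovered, which checks only the code. The simulated regions lay far apart, and the peaks of a region had equal width, a small shift and no missed calls. Full recovery was therefore bound to follow and does not bear on false gained or lost calls in the real lists.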

Results

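Binding of PU.1 was mapped by ChIP-seq in iBN cells, a mouse cell line that the labels describe as a granulocyte-macrophage progenitor, grown in GM-CSF and carrying a doxycycline-inducible PU.1 system. PU.1 is an ETS-family transcription factor of myeloid and B-lymphoid cells. Induced cells had received 1000 ng per ml of doxycycline for 72 hours, and uninduced cells had not been treated. There were 2 PU.1 ChIP libraries per condition, each with its own list of peaks, and 1 further list per condition that the authors had merged. The lists cover chromosomes 1 to 19 and X in mouse build mm9, and only the uninduced lists hold peaks on Y (5 in replicate 1, 1 in replicate 2 and 7 in the merged list). All positions below are in that build, counted from 1. Induced replicate 1 held 68076 peaks, induced replicate 2 held 57336, uninduced replicate 1 held 31960 and uninduced replicate 2 held 42951. The read depth behind each list is unknown, and no gene annotation of mm9 was used here, so binding regions are named by position.

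The first comparison asked whether induction changed the extent of PU.1 binding. The induced libraries held 62706 ± 7594 peaks (mean ± SD, n = 2) and the uninduced libraries 37456 ± 7772 (n = 2), a ratio of 1.67. Peaks covered 71.0 ± 11.9 Mb in the induced and 36.6 ± 6.95 Mb in the uninduced libraries, a ratio of 1.94. The median width of peaks was 1002.5 and 965.0 bp in the 2 induced libraries and 943.0 and 895.0 bp in the 2 uninduced ones. Both induced libraries exceeded both uninduced libraries in each of these measures. The exact permutation test gave a two-sided p of 0.333 for peak number, covered length and median width, which is the smallest that 2 libraries against 2 allow, so none of them could pass a threshold of 0.05. The labels do not say whether replicates came from separate cultures, so the spread between them may be technical.

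**Figure D1:**
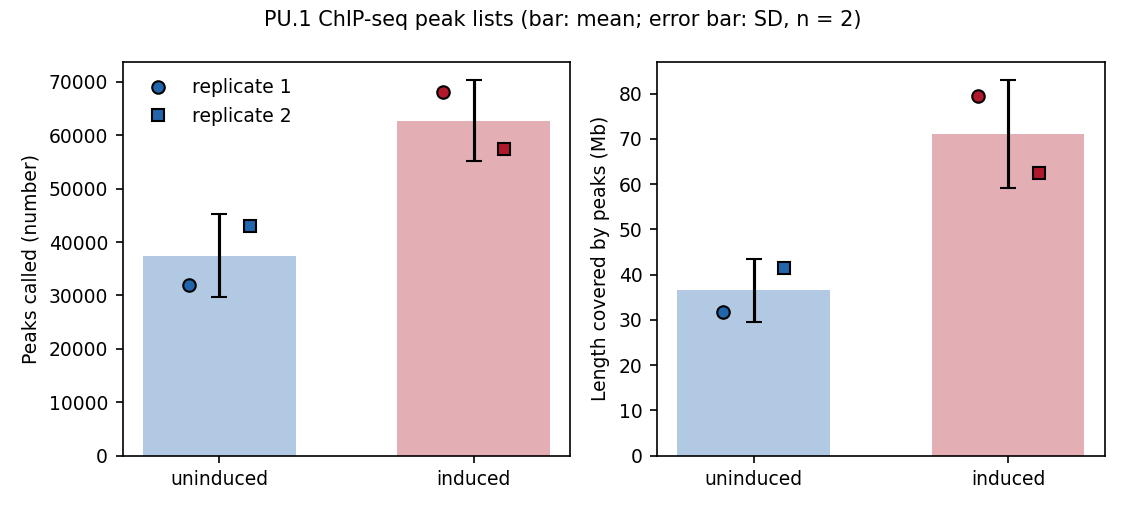
Number of peaks (left) and length covered by peaks in Mb (right) in the uninduced and induced PU.1 ChIP libraries; points are libraries, bars the mean and error bars the SD of 2 libraries. Both induced libraries lie above both uninduced ones, with means of 62706 against 37456 peaks.

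The induced replicates overlapped each other more than the uninduced replicates did. Of the peaks of induced replicate 2, 92.4% (95% Wilson interval 92.2 to 92.7%) overlapped a peak of induced replicate 1 by at least 1 bp, and 76.3% (75.9 to 76.6%) did so in the other direction. Of the peaks of uninduced replicate 1, 77.5% (77.1 to 78.0%) overlapped uninduced replicate 2, and 57.9% (57.5 to 58.4%) did so in the other direction. Uninduced replicate 2 overlapped the longer lists of induced replicates 1 and 2 more than its own replicate, with 82.8% and 78.5% of its peaks. For uninduced replicate 1 these shares were 73.6% and 69.7%, below its overlap with uninduced replicate 2. With each list limited to its 31960 best-scoring peaks, the length of the shortest list, the mean overlap was 88.8% between the induced and 66.0% between the uninduced replicates. There is 1 pair of replicates per condition, so this difference has no replicate check, and the intervals cover counting error only.

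The central comparison asked which sites had a peak in 1 condition and not in the other. The peaks of the 4 libraries merged into 82810 regions. Of these, 19391 (23.4%) had a peak in all 4 libraries and are called shared. A further 18414 (22.2%) had a peak in both induced and in neither uninduced library and are called gained, and 3150 (3.8%) had a peak in both uninduced and in neither induced library and are called lost. The other 41855 regions were mixed. The largest mixed groups were 12736 regions found only in induced replicate 1 and 12052 found in both induced libraries and in uninduced replicate 2. Of the 24146 regions found in both uninduced libraries, 80.3% were found in both induced libraries and 13.0% in neither. Of the 51291 regions found in both induced libraries, 35.9% were found in neither uninduced library.

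Gained regions outnumbered lost regions 5.85 to 1. The split of the libraries by condition separated 21564 regions, whereas splitting them by replicate number separated 1144 and the crossed split 1695. The split by condition also sets the 2 longest lists against the 2 shortest, which adds to its count. The splits were not recomputed with lists of equal length. No p-value is given, because presence and absence in 2 libraries against 2 cannot pass a threshold. The excess was smaller with lists of equal length: with 31960 peaks per library, 6480 regions were gained and 4443 lost, a ratio of 1.46. Equal lists draw the counts of gained and lost regions together by construction. The ratio therefore does not show how much of the excess is due to list length. Without uninduced replicate 2, 30507 regions were gained at a ratio of 3.97, and without induced replicate 2, 31417 were gained at a ratio of 8.73. Without uninduced replicate 1, 6590 regions were lost, 31461 were shared and the ratio was 3.02, and without uninduced replicate 2 the lost regions numbered 7676. Leaving out a library raises these counts by itself, since each class then rests on fewer libraries. With peaks scoring at least 100 only, 742 regions were lost, 11487 were shared and the ratio was 18.28.

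**Figure D2:**
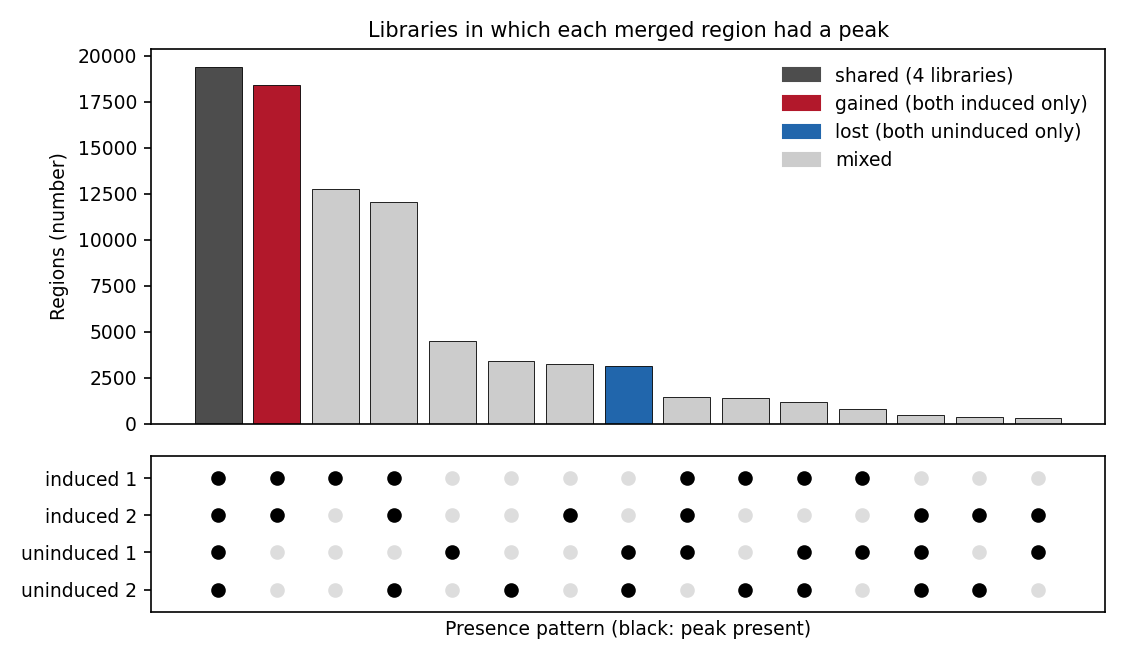
Number of merged regions (y axis) for each of the 15 presence patterns over the 4 libraries (black dots mark a peak in that library). Shared regions (19391) and gained regions (18414) form the largest patterns, while lost regions number 3150.

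The strongest gained region lay at chromosome 18, 23261180 to 23263250, with scores of 3002.05 and 2435.33 in induced replicates 1 and 2 and no peak in either uninduced library. It was followed by chromosome 10, 42571822 to 42573158, with scores of 2273.56 and 1732.83, and by chromosome 10, 118250654 to 118252669, with scores of 2118.9 and 1429.53. Next came chromosome 8, 39139328 to 39141390 (1677.36 and 1374.73), and chromosome 3, 96393690 to 96394953 (1629.14 and 1319.05). The region at chromosome 12, 106480879 to 106482670, scored 1779.36 and 1236.73, and that at chromosome 3, 89776684 to 89779258, scored 1755.84 and 1230.07. The last 3 of the 10 strongest were chromosome 6, 141863771 to 141865146 (1245.62 and 1227.17), chromosome 12, 10761515 to 10762694 (1116.31 and 1252.46), and chromosome 3, 88263148 to 88266283 (1672.28 and 1084.03). All 10 had a peak in the authors' merged induced list and none in their merged uninduced list. The 3 on chromosome 3 lie between 85 and 120 Mb, where shared regions also ranked higher in the induced libraries. The scores are the authors' own, 1 per peak. The order of the named regions rests on the lower of 2 scores from lists with different score levels (medians of 164 and 140 in the 2 induced lists), so it is only a rule for naming regions.

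Lost regions scored low within the uninduced lists, with median scores of 74.2 and 68.2 in uninduced replicates 1 and 2 against 172 and 242 for shared regions. The strongest lay at chromosome 10, 63100339 to 63101468, with scores of 558.01 and 315.51 in uninduced replicates 1 and 2. The others were chromosome 16, 37185869 to 37186927 (357.36 and 303.42), chromosome 10, 22025840 to 22026730 (399.21 and 269.68), chromosome 14, 26673278 to 26674303 (215.47 and 213.98), and chromosome 11, 8956727 to 8957660 (565.76 and 212.39). The regions on chromosomes 16 and 14 did have a peak in the authors' merged induced list. Both uninduced scores reached 100 in 181 lost regions (5.75%). A peak in the other condition's merged list was present for 725 gained regions (3.94%) and 244 lost regions (7.75%), which leaves 17689 gained and 2906 lost regions without one.

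Shared regions held the highest scores. In 95 of them the lower of the 2 induced scores was exactly 3100, a value that many of the highest-scoring peaks carried, and these ties were ordered by the higher of the 2 scores. The value may be a limit of the score's scale rather than a measured strength, although some peaks scored above it, so the order among these regions is uncertain. The region at chromosome 4, 94772192 to 94773808, came first, with scores of 3100 and 3233.06 in the induced and 526.71 and 1945.61 in the uninduced libraries. The next were chromosome 6, 124958127 to 124960778, chromosome 11, 98800760 to 98806698, chromosome 11, 87561392 to 87566059, and chromosome 11, 69221791 to 69226416. They were followed by chromosome 19, 18704602 to 18706899, chromosome 8, 28369501 to 28373130, chromosome 3, 95475314 to 95481774, chromosome 2, 22628538 to 22631443, and chromosome 9, 57491259 to 57495308. Across these 10 the scores ran from 341.58 to 3100 in uninduced replicate 1 and from 473.16 to 3100 in uninduced replicate 2. The region on chromosome 2 was at 3100 in both uninduced libraries.

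Uninduced peaks with higher scores were more often found in both induced libraries. In uninduced replicate 1, 67.3% of peaks overlapped peaks of both induced libraries, with a median score of 155, and 7676 peaks overlapped neither, with a median score of 69.2. The area under the curve, the chance that a peak kept in both outscored one found in neither, was 0.810 (95% interval from resampled chromosomes 0.805 to 0.814). In uninduced replicate 2, 76.6% were kept, with a median score of 155, and 15.3% were in neither, with a median of 64.9, which gave an area of 0.853 (0.849 to 0.858). In the highest score decile 99.4% of peaks of uninduced replicate 1 and 99.95% of uninduced replicate 2 were found in both induced libraries. In the lowest decile the shares were 40.0% and 45.0%. Peaks are not independent replicates, so the intervals describe these libraries. Of all peaks, 14.1% of uninduced replicate 1 and 7.98% of uninduced replicate 2 were found in no other library, the other uninduced one included. No area was computed for overlap with the other uninduced replicate, so these values do not show an effect of induction.

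**Figure D3:**
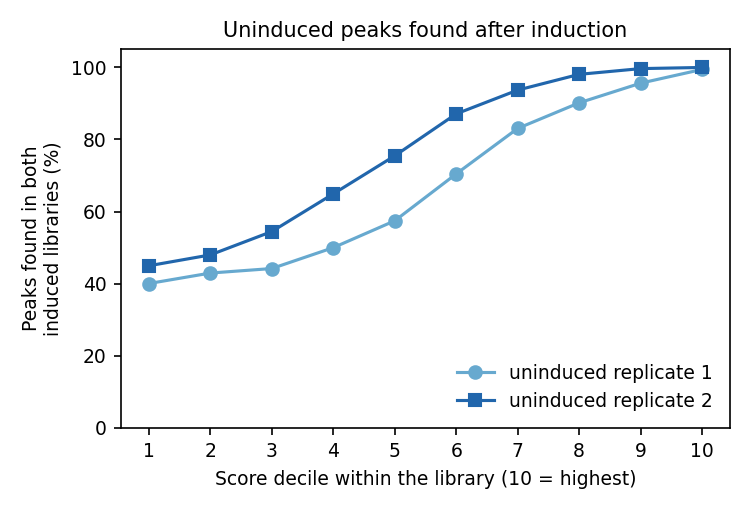
Share of uninduced peaks found in both induced libraries (%, y axis) against the score decile within each uninduced library (x axis, 10 is the highest). The share runs from 40.0% and 45.0% in the lowest decile to 99.4% and 99.95% in the highest.

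Peaks in gained positions scored lower than peaks in shared positions within the induced libraries. In induced replicate 1 the median score was 491 for peaks in shared and 137 for peaks in gained positions, with an area under the curve of 0.831 (0.826 to 0.837). In induced replicate 2 the medians were 314 and 94.2, with an area of 0.828 (0.822 to 0.835). Peaks in gained regions were also narrower, with a median width of 962 bp against 1203 bp in shared regions in induced replicate 1, and 890.0 bp against 1094 bp in induced replicate 2. Peaks in lost regions had a median width of 796 bp against 1023 bp in shared regions in uninduced replicate 1, and 701 bp against 1007 bp in uninduced replicate 2. These widths carry no test. A shared position had to pass the authors' threshold in every library, whereas a gained position had no called peak in either uninduced library. Strong sites are more likely to pass in every list, so lower scores and widths in gained positions can follow from this definition alone. The areas do not show that gained sites are a weaker kind of binding. The same limit applies to the lower scores and widths of lost regions.

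Gained sites lay near shared sites more often than rotated positions did. Within 10 kb of a shared region lay 33.1% of the gained regions, against a mean of 13.7% (range 12.3 to 15.5%) when the gained regions were rotated along their chromosomes 1000 times, a permutation p of 0.001, the smallest that 1000 rotations can give. Of the lost regions 9.65% lay within 10 kb of a shared region, below the rotation mean of 12.6% and below its range of 10.5 to 14.8%. Rotation compares with positions anywhere on the chromosome, mappable or not, and does not correct for gene-rich segments.

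Gained regions were spread over the chromosomes unevenly. Relative to shared regions, they were over-represented on 4 of the 20 chromosomes tested (3, 18, 19 and X) and under-represented on 3 (2, 7 and 15) by Fisher's exact test with Benjamini-Hochberg adjustment. Chromosome 19 held 4.70% of gained and 3.37% of shared regions (odds ratio 1.41, exact test, adjusted p = 1.07e-09), and chromosome 3 held 5.91% and 4.72% (odds ratio 1.27, adjusted p = 2.97e-06). Of all peaks, chromosome 19 held 3.77% and 3.79% in the induced against 3.02% and 2.88% in the uninduced libraries, whereas chromosome X held 1.81% and 1.64% against 2.75% and 2.25%, and chromosome 3 held 5.11% and 5.06% against 5.35% and 4.64%. Neighbouring regions are not independent: when each window of 100 kb was counted once per class, no chromosome passed for gained regions, with odds ratios of 1.13 for chromosome 19 and 1.01 for chromosome 3. Without uninduced replicate 2, only chromosomes 19 (1.15, adjusted p = 0.045) and X (1.35) passed by Fisher's exact test, and chromosome 3 was at 1.04. With lists of equal length, chromosomes X (1.04, adjusted p = 0.777), 18 (1.07, adjusted p = 0.580) and 15 (0.873, adjusted p = 0.172) did not pass by Fisher's exact test. Chromosome 18 also did not pass with an overlap of 50% of both intervals, chromosomes 15 and 18 with peaks scoring at least 100, and chromosome 2 without induced replicate 2.

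For lost regions, 4 chromosomes (1, 3, 14 and X) were over-represented and 5 (2, 9, 11, 17 and 19) under-represented relative to shared regions. Lost regions were over-represented on chromosome X, with 6.35% of lost against 1.36% of shared regions (odds ratio 4.91, exact test, adjusted p = 1.08e-52). They were under-represented on chromosome 11, with 3.49% against 7.03% (odds ratio 0.478, exact test, adjusted p = 1.49e-14), and on chromosome 19, with 1.68% against 3.37% (odds ratio 0.490, exact test, adjusted p = 5.04e-07). With windows of 100 kb counted once per class, chromosomes X (odds ratio 3.42), 11 (0.529) and 19 (0.556) passed. The odds ratio of chromosome X was 2.28 with lists of equal length and 2.05 with peaks scoring at least 100, where chromosome 3 turned to 0.92 and did not pass. Chromosomes 1, 2 and 9 did not pass with that score either. With lists of equal length, chromosomes 2, 3 and 9 did not pass, and without induced replicate 1 chromosome 9 did not. With an overlap of at least 50% of both intervals, chromosome 19 was at 0.822 (exact test, adjusted p = 0.156) and chromosomes 1, 14 and 17 did not pass either.

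**Figure D4:**
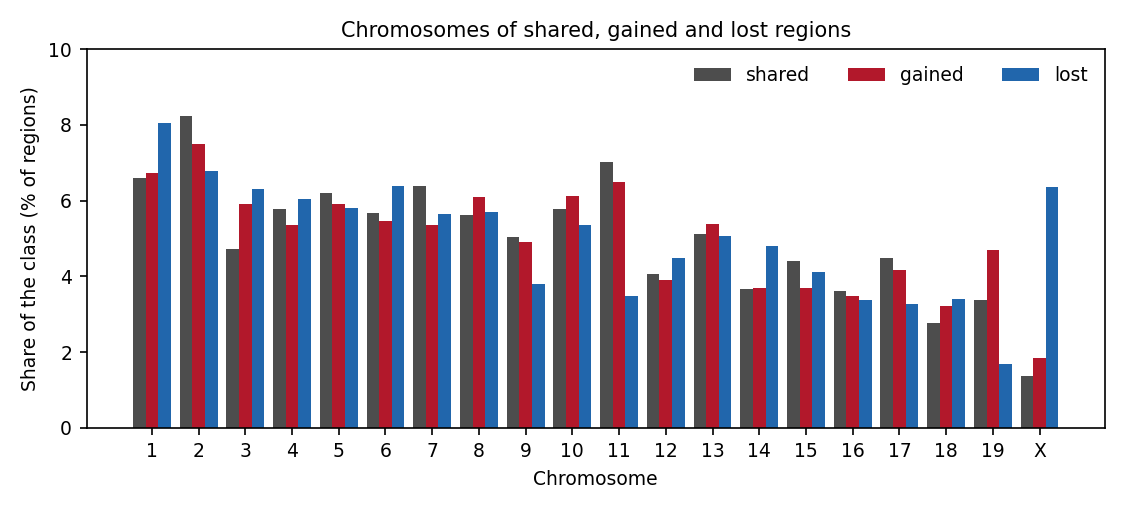
Share of shared, gained and lost regions on each chromosome (% of the regions of that class, y axis). Chromosome 19 holds 4.70% of gained against 3.37% of shared regions, and chromosome X holds 6.35% of lost against 1.36% of shared regions.

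On chromosome 3 the gained regions were concentrated between 85 and 120 Mb, which holds the 6 neighbouring 5-Mb windows with the highest mean rank shift in the genome, leaving out the window at 110 Mb, which had fewer than 10 shared regions. That segment held 568 gained, 313 shared and 31 lost regions, against 520 gained and 603 shared on the rest of the chromosome, and it contains 3 of the 10 strongest gained regions. With the same shared regions ranked by score within each library, those of the segment stood a median of 15.3 percentile points higher in the induced than in the uninduced libraries, and those of the rest of chromosome 3 had a median shift of -2.51 points. The segment was picked for its shift in these libraries, so both values are partly set by that choice and overstate the contrast. Runs of 6 windows above the 95th percentile of windows in random order together spanned 65 to 125 Mb, with a median shift of 8.3 points over 442 shared regions. Such runs also spanned 0 to 50 Mb of chromosome 19, with a median shift of 9.1 points over 552 shared regions. On chromosome 19 the median shift was 8.17 points, and it ranged from 6.18 to 9.49 over the 4 pairs of an induced with an uninduced library.

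**Figure D5:**
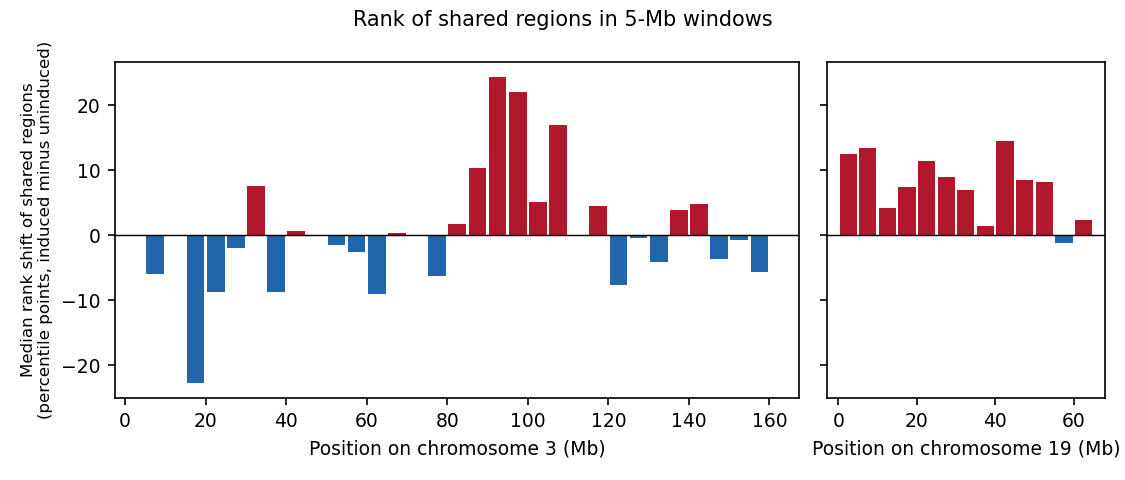
Median shift in score rank of shared regions (percentile points, mean of the 2 induced minus mean of the 2 uninduced libraries, y axis) in 5-Mb windows with at least 10 shared regions along chromosomes 3 and 19 (x axis, Mb). All 6 such windows from 85 to 120 Mb of chromosome 3 and 12 of 13 windows of chromosome 19 lie above 0.

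The authors' merged lists were compared in the same way. The merged induced list held 71582 peaks and the merged uninduced list 44233. In the merged induced list 38227 peaks (53.4%) did not overlap a peak of the merged uninduced list, and 9909 uninduced peaks (22.4%) did not overlap the merged induced list, or 3593 with scores of at least 100 in both lists. Of the merged peaks, 4890 induced (6.83%) and 2492 uninduced (5.63%) overlapped a peak in neither replicate of their condition. The 2 merged lists have no replicates, so no test applies to them.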

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

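Of 228 alternative values over 33 results, 174 kept the label of the main value and 17 counts or ratios moved past a set bound. A further 36, all odds ratios of single chromosomes, kept their direction but no longer passed. Only 1 changed direction: the odds ratio of lost regions on chromosome 3 was 0.92 with a score of at least 100, where fewer regions were tested. Overlaps between replicates, counts of regions, merged peaks or chromosomes, and the block by replicate number could not be labelled as changed in direction. The exclusion of regions with a peak in the other merged list, windows of 100 kb counted once per class and all alternatives for the chromosomes of lost regions were chosen after seeing the data. The ratios of peak number (1.46 to 2.01) and covered length (1.71 to 2.33) stayed above 1, with tests too small to pass. The 4 areas under the curve (0.725 to 0.857) and the excess of gained regions near shared ones (5.86 to 33.6 percentage points, over windows of 2 to 50 kb) kept their side of the threshold. Counts of regions did not hold as well. Lists of equal length gave 6480 gained regions, 1.46 gained per lost region and 4 chromosomes past the threshold for gained regions in place of 7 (15, 18 and X did not pass). A score of at least 100 gave 742 lost regions, 11487 shared regions, 18.28 gained per lost region and 3593 merged uninduced peaks without a merged induced partner; fewer peaks enter under both settings. Leaving out 1 library gave 19869 to 31417 gained, 3598 to 7676 lost and 19989 to 31461 shared regions. Each class then rests on fewer libraries, which by itself raises these counts. The ratio was 3.02 to 8.73 gained per lost region, and 2 to 10 chromosomes were past the threshold for gained regions. What moved the ratio and the number of chromosomes was not tested. The 2 chromosomes were left without uninduced replicate 2 and the 10 without uninduced replicate 1. Counting 100-kb windows once per class left 0 chromosomes for gained regions, and fewer items were tested there. For lost regions, 9 chromosomes passed. With an overlap of 50% of both intervals 6 passed: chromosomes 1, 14, 17 and 19 did not, and a chromosome outside the 9 did. Lists of equal length gave 9 again but not the same ones, since chromosomes 2, 3 and 9 did not pass. The number was 5 with a score of at least 100, 3 with 100-kb windows and 8 to 12 without 1 library. No label says that the replicate numbers mark a shared batch, and the deviations of same-numbered libraries correlated at 0.043 across regions. With the replicate number as a block (replicate block), the mean ratio within pairs was 1.73 for peak number and 2.01 for covered length, with an exact sign-flip p of 0.5, the smallest that 2 pairs allow; it changed no call. Alternatives for the distance of lost regions, promoters, gene lists and the motif were not run. The unknown read depth limits all counts of absent peaks.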

Other observations

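Broad PU.1 peaks of at least 3000 bp were more frequent after induction, a width chosen after seeing the data, as were the windows of 100 kb. Induced replicates 1 and 2 held 1257 and 574 of them (1.85% and 1.00% of their peaks). Uninduced replicates 1 and 2 held 53 and 121 (0.166% and 0.282%). In 500 cases a broad peak of induced replicate 1 overlapped a broad peak of induced replicate 2, against 32 cases between the uninduced replicates. These numbers also depend on how many broad peaks each list holds. The width of a called peak may depend on read depth, which is unknown, so an effect of induction on width is not shown. The broadest after induction, at chromosome 19, 5835070 to 5851434, measured 16365 and 12317 bp in the induced against 5476 and 4622 bp in the uninduced libraries. A second one, at chromosome 15, 19637732 to 19647504, measured 9773 and 9566 bp in the induced libraries and 861 bp in uninduced replicate 2, with no peak in uninduced replicate 1. At chromosome 17, 39979501 to 39986210, all 4 libraries had a peak of similar width, 6577 and 6122 bp in the induced and 6710 and 6510 bp in the uninduced ones. Repeats and regions prone to artifact signal were not filtered out here, so a broad peak need not mean PU.1 binding. The reverse was seen at chromosome 1, 85096145 to 85103164, where peaks of 6256 and 5450 bp in the uninduced libraries had no counterpart in the induced ones. Within induced replicate 1, 4.98% of the peaks in shared regions and 0.303% of those in gained regions were at least 3000 bp wide, and within induced replicate 2 it was 2.31% and 0.134%.

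The densest windows of 100 kb for gained regions held 10 or 11 of them. The first, chromosome 3 from 89700001 to 89800000, held 11 gained and 2 shared regions. Of the 6 densest, 4 lay on chromosome 3 between 88200001 and 96600000, 1 on chromosome 13 from 99900001 to 100000000, and 1 on chromosome 1 from 107800001 to 107900000.

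In the 3 patterns weighed below, the tests of runs of windows, of 100-kb windows and of chromosome length were chosen after the result was seen. The first pattern is the uneven share of gained regions between chromosomes. Denser binding stays open as its cause. The fit on region density was made on the rank shift of shared regions, not on the share of gained regions. After that fit the median rank shift of chromosome 19 lay 5.67 standard deviations above the other chromosomes (6.41 before). Region density thus did not account for the rank shift of chromosome 19. A change in copy number of whole chromosomes stays open, also for chromosome 19, where shared regions shifted by a median of 6.18 to 9.49 points in the 4 pairs of libraries, since the odds ratio and the rank shift correlated weakly over the 20 chromosomes (rho = 0.087, permutation p = 0.713; Pearson r = 0.444, permutation p = 0.057, and 0.198 without the 2 chromosomes farthest from the median odds ratio). A candidate explanation for chromosome 3 from 85 to 120 Mb is a copy number that differs between the induced and the uninduced cells: over 6 neighbouring windows, with the sparse one at 110 Mb left out, the shared regions shifted by a mean of 13.9 points, against at most 11.5 in 1000 random orders (permutation p = 0.001, the smallest they can give). Runs on chromosome 19 from 0 to 50 Mb also exceeded the 95th percentile of the random orders, so chromosome 3 was not alone. Coordinated binding over either segment would give the same shift. Dense clusters stay open too, since 0 chromosomes stayed past the threshold with 100-kb windows counted once, although 12 of 13 windows of chromosome 19 had a gained share above the median window.

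The second pattern is that 12052 regions of both induced libraries were found in uninduced replicate 2 alone of the uninduced libraries, and 1434 in uninduced replicate 1 alone. Weak peaks near the authors' threshold in replicate 1 stay open: of its 10000 best-scoring peaks 0.36% were found in no other library, but peaks that replicate 1 holds do not bear on regions that it lacks. A longer list in replicate 2 was not decided: among the 10000 best-scoring peaks of each, 99.7% of replicate 2 and 94.7% of replicate 1 were found in both induced libraries, a difference of 4.94 percentage points where 5 had been set as the bound. A biological difference between the 2 uninduced samples was not tested, since no label separates them.

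The third pattern is the high share of lost regions on chromosome X. Weak peaks falling there in every library were examined through regions found in only 1 library, which were not chosen by score. Those found only in induced replicate 1 had 2.30% on chromosome X and those only in induced replicate 2 had 1.51%. Both lie below the interval of the lost regions (5.55 to 7.26%). Those found only in uninduced replicates 1 and 2 had 6.97% and 5.60%. Single-library regions thus did not have a high share on chromosome X in every library. They need not be peaks near the threshold, so where such peaks fall stays open. The lost regions may also be spread by chromosome length, as background calls would be: chromosome X makes up 6.31% of the summed spans, and the span share of 17 of 20 chromosomes lay within the interval of their share of lost regions. The misses all held fewer lost regions than their length: chromosomes 9 (3.81% against 4.70% of the spans), 11 (3.49% against 4.62%) and 19 (1.68% against 2.33%). Regions found only in 1 induced library also lay below the span share of chromosome X, so they were not spread by length there. Whether induction removed PU.1 from these sites stays open.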
